A study of Mus musculus with 6 samples.

How the data were processed

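The data are gene counts and FPKM (counts scaled by gene length and library total) from RNA sequencing of 3 control and 3 PDTLN1-treated libraries of P19 cells, made with an Illumina TruSeq RNA kit per the labels' protocols. The counts deposited by the authors are whole numbers per gene and library, not normalized, for 34745 genes, per the file headers and the values. The FPKM values deposited by the authors follow the counts: for all 15678 genes with counts in every library, count and FPKM implied 1 gene length in all libraries within 0.1%, so FPKM carried no further information and only the counts were tested. Per the submitters' processing notes, Bowtie 0.12.2 was named together with the builds mm8 and mm9, with no role given. The counter, its treatment of strand and of reads with several matches, and the annotation are not given in the sources used here. Gene positions in the table were compared with GENCODE mouse release 21 (build GRCm38): of 34344 identifiers found there, 27776 (80.9%) had the same chromosome, start and end, so coordinates are given in GRCm38. GC content and 3' UTR lengths came from that annotation, and gene lengths were those implied by the counts and FPKM. Without knowledge of strand and multiple matches, counts of overlapping genes, antisense genes, gene families and genes with pseudogenes are uncertain.

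Samples were grouped by the treatment in their labels, and table columns were assigned by sample title. In those titles the treated samples carry a code, P50, that is not explained; the treatment label was used. The groups share replicate numbers, with no label saying that a number marks a shared culture or day, so the number was not in the model. The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made after.

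Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group kept 13836 genes, TMM factors scaled the libraries, and glmQLFit with robust estimation and glmQLFTest gave two-sided p-values, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM values use the scaled library sizes, except in the rule for genes at 2 levels and for its examples, which use the unscaled library totals. The SE of a log2 fold change was the fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.126. For 36 gene lists, 34 of which had at least 5 tested members, limma 3.58.1 ran camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, camera with an estimated correlation, and fry. Fry's directional test asks whether a list moves one way on balance, and neither of its tests compares a list with other genes. Members were also adjusted over each list alone.

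Named are, per direction, the 8 genes with the largest fold change among those that passed with no overlap between the groups, the same among genes above the median level, up to 4 members of each list with the smallest p, and Tln1, Actb and Gapdh. Where fewer than 8 passed, the genes with the smallest p fill the place and are said to have not passed. Genes with only a predicted or clone name are counted and not named, and members of lists with fewer than 3 changed genes were partly left out. Other list members, and genes that illustrate the 2-level pattern, were chosen after their values were seen.

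The alternatives were the replicate number as a block, leaving out each library, the DESeq2 1.42.0 Wald test, DESeq2 size factors, no scaling beyond library size, no filter beyond a count in 1 library, a stricter filter (at least 1 CPM in 3 libraries and 10 counts in each library of a group), thresholds of 0.01 and 0.1, and for lists the other tests named above. A pseudocount alternative applied to normalized values only and was not needed. Added after seeing the data were 2 against 2 libraries, the first principal component as a covariate, and leaving out genes at 2 levels. A gene was said to sit at 2 levels when, at a mean of at least 10 CPM, the widest gap between its sorted log2 values (pseudocount 0.5 CPM) was above 0.6 and above 4 times the SD within the levels. All 10 splits of the libraries into 3 and 3 were refitted. Trends of GC content and length were removed with mgcv 1.9.3, and libraries were thinned to the smallest total.

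The steps were tested on simulated data for the PDTLN1 comparison with 13836 genes. Of 50 genes changed per size, edgeR recovered 46% at 1.5-fold, 76% at 2-fold, 98% at 3-fold and 96% at 4-fold, with 14 false among 172 calls. The adjustment is looser with more calls, so recovery among fewer changed genes would be lower. Camera called 3 of 3 lists moved by 0.5 log2 units and 0 of 31 others. Genes were simulated independently of each other, so this does not show how often camera calls lists of correlated genes. The 2-level rule found 94 of 100 genes put at 2 levels and 34 among 9937 genes with none put in. The totals of 10381307 to 11663081 counts per library gave a median SE of 0.13 log2 units per gene. Counting intervals and floors cover counting error only.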

Results

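RNA sequencing gave 6 libraries of P19 cells, a mouse embryonal carcinoma line that can be driven towards cardiac or neural fates. The labels describe 3 libraries as untreated controls and 3 as treated with the peptide PDTLN1, and give neither the dose nor the duration of treatment. Total gene counts were 10450134, 10692451 and 11177756 in control libraries 1, 2 and 3, and 10381307, 11515237 and 11663081 in PDTLN1 libraries 1, 2 and 3. Mitochondrial transcripts took between 3.46% and 4.01% of the counts. Every pair of libraries differed by more than counting noise, and their log2 CPM (counts scaled by library size) correlated at 0.981 to 0.988 across genes, which are not independent replicates. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which is possibly technical.

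Markers of pluripotent cells were expressed in all 6 libraries. Pou5f1, the transcription factor at the centre of the pluripotency network, was at 1465 ± 32.6 CPM in controls (SD, n = 3) and 1353 ± 83.4 CPM after PDTLN1 (SD, n = 3). Lin28a, an RNA-binding protein of pluripotent and germ cells, was at 918 ± 38.1 and 911 ± 41.8 CPM, (SD, n = 3 each), and Nanog averaged 97.6 and 90.1 CPM. The extraction text in the labels speaks of retinas, a tissue other than the one the samples are labelled with. Of photoreceptor genes, Crx and Arr3 had 0 counts in all 6 libraries, which allows a level of up to 0.256 to 0.290 CPM (3 counts per library). Of 23 retinal genes, 3 (Abca4, Rom1 and Guca1a) had enough counts to test, and of 15 blood and immune genes, 4 did.

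The comparison of PDTLN1 with control asked which genes the peptide induces or represses in P19 cells. Dcbld2, which encodes a membrane protein with CUB and LCCL domains, rose 3.17-fold, from 47.7 ± 3.49 to 151 ± 3.82 CPM (SD, n = 3 each). Ipmk, the inositol polyphosphate multikinase, rose 2.73-fold, from 23.9 ± 2.37 to 65.3 ± 5.53 CPM. Ppp1cb, a catalytic subunit of protein phosphatase 1, rose 1.96-fold, from 155 ± 13.3 to 303 ± 39.1 CPM. No gene fell past edgeR's threshold, with 234 lower at an unadjusted p under 0.05 and 5 called lower by DESeq2. These 3 genes, out of 13836 tested, were the full set at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and Dcbld2 and Ipmk changed at least 2-fold.

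The log2 fold change of Dcbld2 (ENSMUSG00000035107) was 1.67 with an SE of 0.08, and edgeR's adjusted p was 4.92e-05. The gene lies on chromosome 16 from 58408443 to 58469727 on the plus strand, in coordinates of the mouse build GRCm38. Ipmk (ENSMUSG00000060733), on chromosome 10 from 71347763 to 71433327, had a log2 fold change of 1.45 with an SE of 0.11 and an edgeR adjusted p of 0.00178. Ppp1cb (ENSMUSG00000014956), on chromosome 5 from 32458843 to 32517433, had a log2 fold change of 0.97 with an SE of 0.10 and an edgeR adjusted p of 0.0459. With the replicate number as a block, the adjusted p was 0.122 for Ipmk and 0.449 for Ppp1cb, the highest over their alternatives, which began at 3.31e-24 and 3.10e-13. All 3 genes were higher in each of the 3 PDTLN1 libraries than in any control library. They also belonged to a set of 162 genes, out of 9926 examined, whose libraries sat at 2 tight and separate levels, mostly in groupings other than treatment; a large and even change between the groups meets the same rule.

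**Figure D1:**
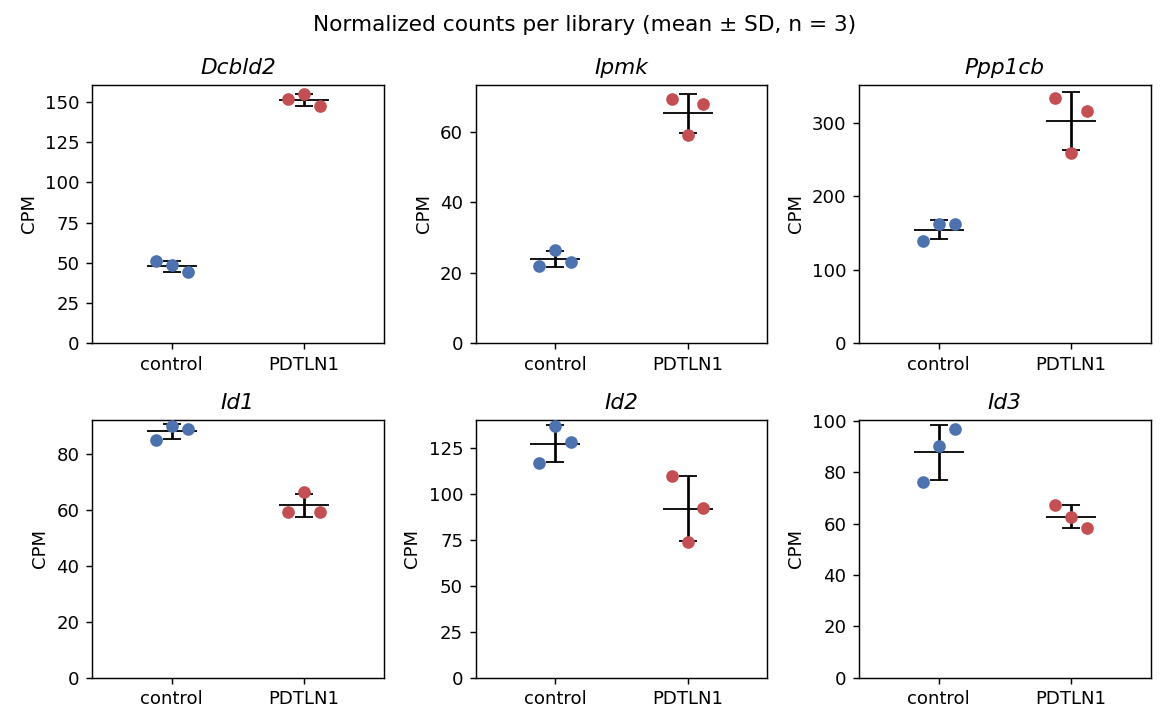
Normalized counts (CPM, linear axis from 0) of 6 genes in control (blue) and PDTLN1 (red) libraries; points are libraries, bars the mean ± SD of 3. Dcbld2, Ipmk and Ppp1cb, which passed the test over all genes, averaged 151, 65.3 and 303 CPM after PDTLN1, and Id1, Id2 and Id3, which passed edgeR's test of all 6 libraries with adjustment over their list alone and not over all genes, averaged 61.5, 92.0 and 62.6 CPM.

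Among genes with lower values after PDTLN1, the smallest p-values belonged to genes that did not pass the adjustment over all genes. Tmem70, which encodes an assembly factor of the mitochondrial ATP synthase, was at 27.7 ± 1.84 CPM in controls and 15.5 ± 1.17 CPM after PDTLN1 (SD, n = 3 each), a log2 fold change of -0.84 with an edgeR adjusted p of 0.112. Fscn1, the actin-bundling protein fascin, averaged 304 and 213 CPM, with libraries at 282 to 333 and 207 to 221 CPM, a log2 fold change of -0.51 with the same edgeR adjusted p of 0.112. Stau1, a double-stranded RNA-binding protein, had a log2 fold change of -0.55, the spliceosomal protein gene Snrnp25 one of -0.49, the sialic acid synthase gene Nans one of -0.32 and the potassium channel gene Kcnn3 one of -1.73. Ube2s, Pml and the pluripotency gene Utf1 had log2 fold changes of -0.60, -0.47 and -0.38. At an unadjusted p under 0.05 edgeR gave 552 genes, 318 of them higher, against 691.8 expected by chance. The 2 groups did not overlap for 1355 genes, or 9.79% of those tested, where chance gives 10%. DESeq2 called 10 genes, 5 of them lower; those named here are Tmem70, Fscn1, Id1 and Stau1.

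Among genes with higher values that did not pass, Lrp2, the endocytic receptor megalin, was at 399 ± 37.7 CPM in controls and 547 ± 34.3 CPM after PDTLN1 (SD, n = 3 each), a log2 fold change of 0.46 with an edgeR adjusted p of 0.376 and a DESeq2 adjusted p of 0.00372, in a range of 0.00372 to 1.00 over its alternatives. Colec12, a scavenger receptor, had a log2 fold change of 0.32, Greb1 one of 0.37, the kinase gene Rock2 one of 0.23 and the cell adhesion gene Nrcam one of 0.36. The protocadherin gene Pcdhgb6 had a log2 fold change of 0.99, and Zfp82 one of 1.15. Pcdhb21 averaged 3.82 CPM after PDTLN1 and 0.239 CPM in controls, of which libraries 1 and 2 had 0 counts, so its fold is not well defined. It passed without control library 3 (edgeR adjusted p 0.0334, in a range of 0.0334 to 1.00 over its alternatives), and protocadherins sit in clusters of similar or overlapping genes, so their counts are uncertain. Tln1, which encodes the adhesion protein talin 1, had a log2 fold change of 0.04 with an SE of 0.07, and of -0.04 without PDTLN1 library 2. Actb and Gapdh had log2 fold changes of -0.16 and 0.14, with SEs of 0.13 and 0.12. The value of Actb rested on control library 1, at 1493 CPM against 1040 to 1138 CPM in the others, and was 0.02 without it. Gapdh, a gene with many processed pseudogenes, averaged 49.6 CPM in controls, and its log2 fold change was 0.01 without PDTLN1 library 3, 0.07 without control library 3 and 0.22 without PDTLN1 library 1.

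Targets of the TGF-beta, Nodal and BMP pathways were the 1 list with members past edgeR's threshold adjusted over the list alone. Id1, Id2 and Id3, inhibitors of basic helix-loop-helix transcription factors and direct targets of BMP signalling, were lower in each PDTLN1 library than in any control library. Id1 was at 87.9 ± 2.56 CPM in controls and 61.5 ± 4.10 CPM after PDTLN1, Id2 at 127 ± 9.97 and 92.0 ± 17.9 CPM, and Id3 at 87.7 ± 10.7 and 62.6 ± 4.46 CPM (SD, n = 3 each). Adjusted over the list alone, 4 of 19 tested members passed with lower values, among them Id1, Id3 and Id2 with edgeR adjusted p of 0.00163, 0.00996 and 0.0414 and log2 fold changes of -0.51, -0.49 and -0.47. This adjustment does not correct for the search over 36 lists, so these p-values are too small for a list picked out by its result. Over all genes 0 of the 19 passed with edgeR, and 1, Id1, did with DESeq2, at an adjusted p of 7.73e-04, in a range of 7.73e-04 to 1.00 over its alternatives. The ligand genes Nodal, Bmp4 and Bmp7 had log2 fold changes of 0.00, 0.04 and -0.18, and the feedback inhibitor genes Smad6 and Smad7 ones of -0.09 and -0.18, none past either threshold. As a list, the 19 members did not stand apart from other genes in limma's camera test, with an adjusted p of 0.116 and, with an estimated correlation, 0.481; the mixed fry test, which asks whether members change in either direction, gave 0.00318. With the replicate number as a block, Id1 stayed past the list threshold (adjusted p 0.0169), and Id3 and Id2 did not (0.0643 and 0.0871). Id1 and Id3 stayed past it without any 1 library, and Id2 lost it without control 1, 2 or 3 or PDTLN1 2 or 3 (adjusted p 0.0598, 0.148, 0.119, 0.0642 and 0.126, in a range of 0.00197 to 0.148 over its alternatives). The number of members of all lists past their list alone was 11 without PDTLN1 library 3 and 3 to 5 without any other library.

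Of the 677 tested members of all 36 lists, 0 passed edgeR's adjustment over all genes, with 47 at an unadjusted p under 0.05, and 1 passed with DESeq2. With limma's camera at a preset correlation of 0.01, 2 of 34 lists passed. Cytosolic ribosomal protein genes were lower, with 52 of 63 members below 0, a median log2 fold change of -0.08 and an adjusted p of 7.41e-04; the adjusted p was 0.885 with an estimated correlation. Their mean lay at -0.03 and -0.13 log2 units around its overall mean in PDTLN1 libraries 1 and 2, and at 0.06 in PDTLN1 library 3, no lower than in controls (0.02 to 0.06). Rplp1 and Rps7 had log2 fold changes of -0.17 and -0.15, and such genes share reads with many processed pseudogenes. In a test chosen after the data were seen, 41 of the 63 had positive loadings on the first principal component, which did not follow the labelled treatment (adjusted permutation p 0.0136). That permutation ignores correlation between the members, so its p is too small. Extracellular matrix genes were higher, with 21 of 23 members above 0, a median of 0.09 and an adjusted p of 0.00158; the adjusted p was 0.694 with an estimated correlation. Their mean lay at 0.08 and 0.13 in PDTLN1 libraries 1 and 2, and at -0.04 in PDTLN1 library 3, within the controls (-0.09 to -0.03). Among them the basement membrane collagens Col4a2 and Col4a1 had log2 fold changes of 0.26 and 0.21, the collagen cross-linking oxidase gene Lox one of 0.50 and Thbs1 one of 0.30. Both lists lost their place without control library 1 (adjusted p 0.0857 and 0.118) and without PDTLN1 library 2 (0.376 and 0.0878), in ranges of 1.25e-08 to 0.885 and 2.30e-06 to 0.694 over their alternatives. Both also lost it with the 2 libraries numbered 1 left out, a choice made after seeing the data (camera adjusted p 0.125 and 0.454). The number of lists past camera was 7 without PDTLN1 library 1 and 1 without PDTLN1 library 2. No list passed fry's directional test, with 5 at an unadjusted p under 0.05, and 3 passed its mixed test: endoderm genes (adjusted p 0.00218), the TGF-beta, Nodal and BMP targets, and primitive streak and mesoderm genes (0.0449). The endoderm and the primitive streak lists share Pdgfra, the member with the smallest edgeR p in both (unadjusted 0.00676), so they are not separate results. Pdgfra was the 1 of 13 tested primitive streak genes at an unadjusted edgeR p under 0.05. Of the 8 tested endoderm genes, 2 were, Pdgfra and Col4a1.

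**Figure D2:**
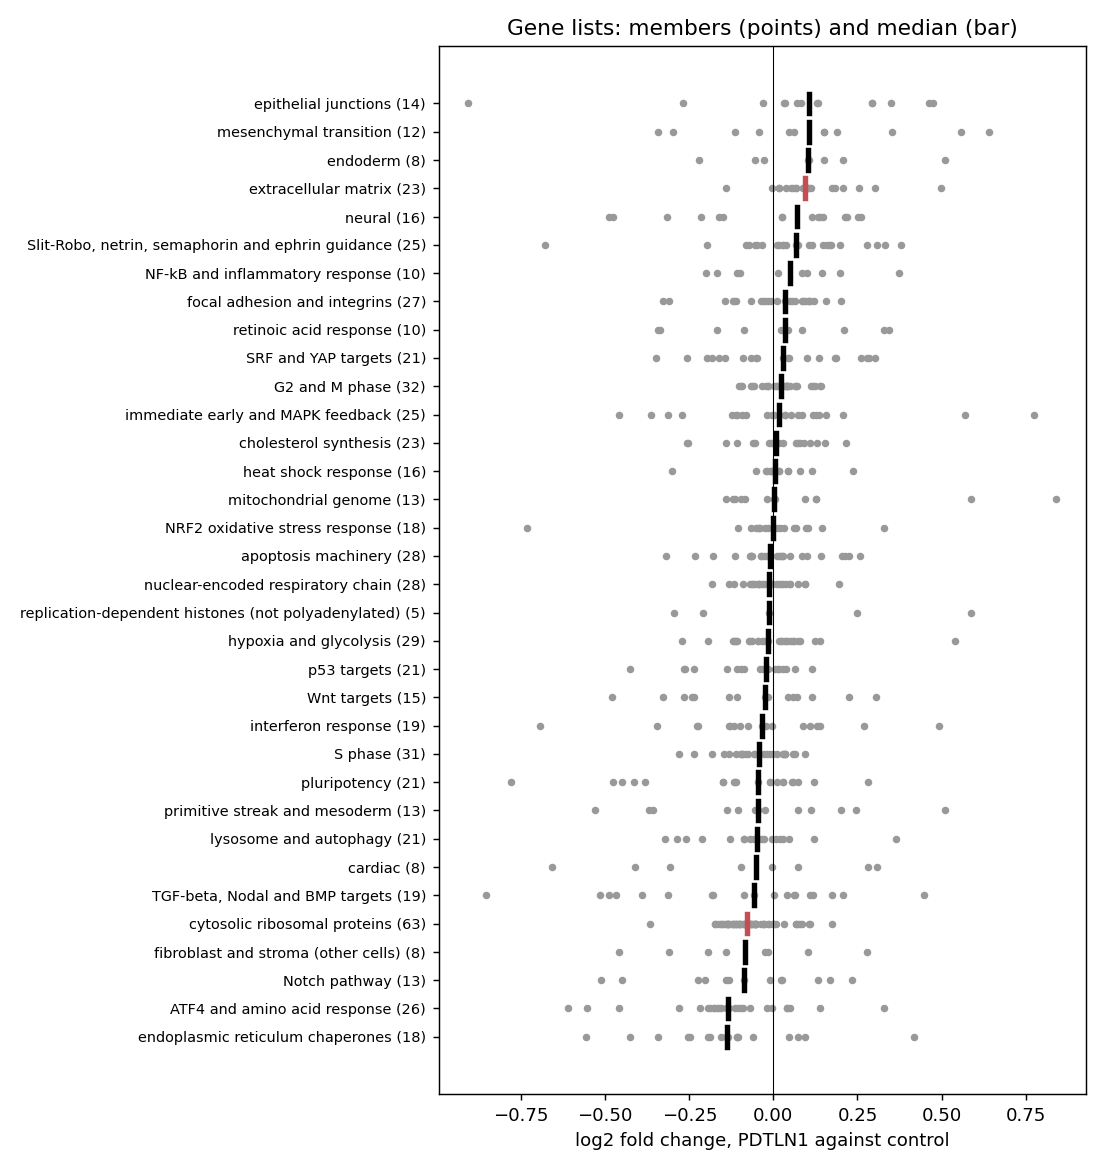
Log2 fold change of PDTLN1 against control (x axis) for the tested members of 34 gene lists, with the number tested in brackets. Points are genes and bars are list medians, red where camera with a preset correlation passed; the medians run from -0.14 for endoplasmic reticulum chaperones to 0.11 for epithelial junctions.

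The germ layer and cell state lists held no changed member. Of 21 tested pluripotency genes, 13 lay below 0 with a median log2 fold change of -0.05; Utf1 and Nr0b1, at -0.38 and -0.45, had the smallest p-values. Pdgfra, a receptor of mesoderm and primitive endoderm, was at 6.52 ± 0.295 and 9.29 ± 0.515 CPM, a log2 fold change of 0.51 that did not pass. The medians were -0.05 for 8 cardiac genes, 0.07 for 16 neural genes, whose mean was -0.02, and 0.03 for 10 retinoic acid response genes, for which camera's direction was down. The mesenchymal list had a median of 0.11 over 12 tested members, 8 above 0 and 4 below. Among its higher members Zeb1, Prrx1 and Cdh11 had log2 fold changes of 0.56, 0.64 and 0.35, none past the threshold. Focal adhesion genes, the list that holds Tln1, had a median of 0.04 over 27 members. Of guidance genes, Efna5 and Sema3c stood at 0.28 and 0.33, Efna1 at -0.68, and the median of 25 was 0.07. Proliferation genes had medians of -0.04 (31 of S phase) and 0.02 (32 of G2 and M phase), and p53 targets and heat shock genes of -0.02 and 0.01.

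Stress genes varied between libraries without following the labelled treatment; an exchange of the libraries numbered 1 was not excluded. The 26 genes of the ATF4 and amino acid response averaged -0.29, 0.17 and 0.39 log2 units around their own mean in control libraries 1 to 3, and 0.40, -0.46 and -0.21 in PDTLN1 libraries 1 to 3. The 18 endoplasmic reticulum chaperone genes averaged -0.19, 0.05, 0.35, 0.25, -0.22 and -0.24 in the same order. Neither list passed camera (adjusted p 0.239 and 0.116; 0.920 for both with an estimated correlation). Both were lower after PDTLN1 without control library 1 (adjusted p 0.0187 for both) and without PDTLN1 library 1 (8.97e-04 for both), and without control library 3 their medians were 0.02 and -0.02 (0.937 for both). On the first principal component, which held 35.0% of the variance, control library 1 lay at -17.0 with PDTLN1 libraries 2 and 3 at -23.5 and -11.7, while control libraries 2 and 3 lay at 14.2 and 19.8 with PDTLN1 library 1 at 18.3. With both libraries numbered 1 left out, a choice made after seeing the data, edgeR called 91 genes, 50 higher and 41 lower, among them Dcbld2, Ipmk, Ppp1cb, Id1, Id2, Id3, Fscn1 and Tmem70. The stress genes Atf4, Atf3, Xbp1, Calr, Slc7a5, Mthfd2 and Dnajb9 were also called. In that fit camera put the ATF4 list (median -0.37, adjusted p 1.48e-06) and the chaperone list (-0.31, 1.40e-05) lower after PDTLN1. The groups left then lay on opposite sides of the first component, so this fit cannot tell treatment from that component.

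**Figure D3:**
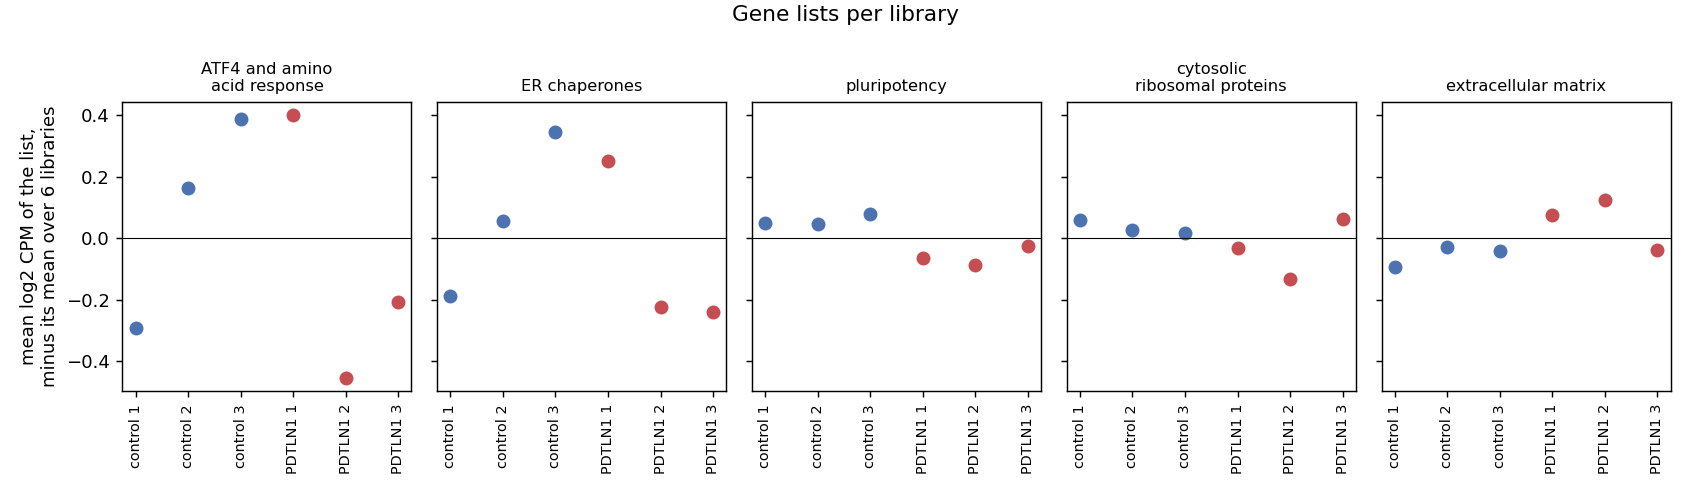
Mean log2 CPM of 5 gene lists in each library, relative to the list's mean over the 6 libraries (y axis, log2 units); blue points are control and red points PDTLN1 libraries. The ATF4 list ranged from -0.46 in PDTLN1 library 2 to 0.40 in PDTLN1 library 1, and the pluripotency list lay at 0.05, 0.05 and 0.08 in controls and at -0.07, -0.09 and -0.02 after PDTLN1.

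The median SE of a log2 fold change was 0.13. In simulated data of this design 76% of 50 genes changed 2-fold and 46% of 50 changed 1.5-fold were recovered, among 172 calls. The libraries themselves gave 3 calls, and with fewer calls the adjustment over all genes asks for a smaller p. Recovery in this comparison would therefore be lower than simulated, and changes of 1.5-fold or less were mostly not detectable. Leaving out 1 library moved the number of called genes from 3 to 13 without control 1, 5 without control 3, 8 without PDTLN1 1, 6 without PDTLN1 2 and 2 without control 2 or PDTLN1 3, of which 6, 0, 3, 3 and 0 were lower; Ppp1cb was lost without control 2, control 3 or PDTLN1 3 (edgeR adjusted p 0.212, 0.0773 and 0.246, in a range of 3.10e-13 to 0.449 over its alternatives).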

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

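The 2 against 2 comparison, the covariate and the omission of genes at 2 levels were chosen after the data were seen; the other alternatives were planned. Dcbld2 passed in all 14 alternatives in which it was tested, with log2 fold changes from 1.61 to 1.71. Ipmk (1.35 to 1.53) failed only in the replicate block, and Ppp1cb (0.82 to 1.07) in the replicate block and without control 2, control 3 or PDTLN1 3. No named gene that passed changed sign. These alternatives all kept the labelled groups, and some other splits of the libraries gave a gene with a smaller p than that of Dcbld2. Of 159 named genes, 10 that had not passed did so under some alternative. DESeq2 size factors, library size alone, the stricter filter and a threshold of 0.1 left 3 genes, and a threshold of 0.01 left 2.

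Same-numbered libraries did not deviate together (r across genes -0.36, -0.14 and -0.10 for numbers 1, 2 and 3), and no control library correlated best with its own number, so no pairing by number was seen. With 3 libraries per group, and those numbered 1 each apart from their group, this check cannot exclude a weaker pairing. With the replicate block, edgeR called 1 gene, 1 higher and 1 at least 2-fold, on fewer residual degrees of freedom. The block left 2 lists past camera and 0 list members past the threshold over all genes.

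Leaving out each library gave 2 to 13 genes, 2 to 7 higher, 0 to 6 lower, 2 to 9 at least 2-fold and 1 to 7 lists. Apart from Fscn1, the genes gained without control 1 were all among the 162 genes at 2 levels. These were Zbtb9, Ramp2, Ahcyl2, Atf7, Dusp3, Pafah1b1, Foxn2, Crk and Ggnbp1. Of the genes gained without PDTLN1 1 or 2, some were (Mfap3, Abl1, Kpna1 and Pvrl3) and others were not (Zfp708 and Banf1). Why the counts moved was not tested further. DESeq2 called 10 genes, 5 higher and 5 lower, 4 of them at least 2-fold, with 1 list member. Without a filter the counts were 8 genes, 4 lower and 1 list member. The 2 against 2 comparison called 91 genes, 50 higher, 41 lower, 28 at least 2-fold and 14 list members. With the first principal component as a covariate the counts were 8 genes, 4 lower and 1 list member. With genes at 2 levels left out, 0 genes were called, 0 higher and 0 at least 2-fold, with 564 at an unadjusted p under 0.05 in edgeR; the rule removes genes with a large and even change between the groups too, so this says nothing about the called genes. An estimated correlation left 0 lists in camera, and directional fry 0, with 1 and 5 at an unadjusted p under 0.05. Adjustment over the list alone gave 4 list members in place of 0, through fewer tests; this count was 1 with the replicate block, 3 to 11 without 1 library, 14 with the covariate, 7 without a filter and 75 in the 2 against 2 comparison. Why the other counts moved was not tested. Depth limits genes of low count most, which was not tested here. The median SE over all tested genes was 0.13 log2 units.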

Other observations

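Except for the splits behind the gene lists and the corrections for GC content, length and depth, the tests in this part were chosen after the results were seen. Several genes of the unfolded protein and amino acid responses varied more between libraries of a group than any called gene did between groups. Ddit3, a transcription factor induced by endoplasmic reticulum stress, was at 10.3, 43.4 and 71.3 CPM in control libraries 1 to 3 and at 66.3, 7.39 and 12.3 CPM in PDTLN1 libraries 1 to 3. Chac1, a glutathione-degrading enzyme downstream of ATF4, was at 16.1, 75.8, 109, 99.1, 12.7 and 20.6 CPM in the same order, and Herpud1, which acts in the degradation of endoplasmic reticulum proteins, at 30.6, 106, 181, 155, 30.8 and 30.9 CPM. Ddit3, Chac1 and Herpud1 were themselves among the 162 genes whose libraries sat at 2 levels, as was the hypoxia gene Ndrg1, so their counts are in doubt too. The 3' UTRs of Ddit3, Chac1 and Herpud1, at 200, 794 and 625 nt, were shorter than those of the called genes. Dcbld2, Ipmk and Ppp1cb had 3941, 4070 and 4468 nt. For Ddit3, Chac1 and Herpud1, a difference in expression between the libraries was not told apart from one in counting. The chaperone gene Hspa5 went the opposite way to Ddit3, Chac1 and Herpud1 over the libraries, at 796, 575, 694, 648, 782 and 744 CPM. It was higher in control library 1 and PDTLN1 libraries 2 and 3 than in the others.

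On the first principal component, 24 of 26 ATF4 genes and 17 of 18 endoplasmic reticulum chaperone genes had positive loadings, the side of control libraries 2 and 3 and PDTLN1 library 1, as did 26 of 29 hypoxia and glycolysis genes and 18 of 21 lysosome and autophagy genes. Mitochondrially encoded genes went the other way, with 11 of 13 negative, and so did 25 of 32 G2 and M phase genes. Of the 63 cytosolic ribosomal protein genes, 41 had positive loadings. Against 10000 random lists matched on mean level, the median loading of the first 4 lists and of the mitochondrial list gave a permutation p of 0.0002, the smallest these can give, or 0.00136 adjusted over 34 lists, and the ribosomal and the G2 and M lists adjusted permutation p of 0.0136 and 0.0194. The component was computed from these same genes, and the random lists ignore correlation between members. Camera estimated that correlation at 0.56 for ATF4, 0.72 for chaperone and 0.67 for hypoxia and glycolysis genes. A list whose members vary together can thus pass, so these p-values are too small. Glycolysis and hypoxia genes differed most between PDTLN1 libraries 1 and 2: Ndrg1 was at 91.8 and 16.9 CPM and the glucose transporter gene Slc2a3 at 2321 and 1243 CPM.

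The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The labelled split called 3 genes, and 4 of the 10 splits, itself included, called as many, the highest other with 831. In 1 direction, 2 splits reached its 3 higher genes (highest other 434), and all 10 its 0 lower genes (highest other 434). At least 2-fold, 7 splits reached its 2 genes (highest other 68). For gene lists past camera, 8 splits reached its 2 (highest other 7), for list members over all genes all 10 reached 0 (highest other 75), for members adjusted over their list alone 2 splits reached its 4 (highest other 115), and for lists past mixed fry 2 splits reached its 3 (highest other 24). The smallest unadjusted p in edgeR was 3.56e-09 in the labelled split, for Dcbld2. It ran from 3.20e-10 to 9.22e-07 over the other splits. In the split of control 1, control 3 and PDTLN1 3 against the rest, which called 2 genes, it was 1.59e-09. A p as small as that of Dcbld2 thus also arose in groupings other than treatment.

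The 3 called genes sat at 2 tight levels, a rule that a large and even change between groups also meets, as did 162 of 9926 genes in all, against 34 in simulated libraries with none put in. Of the 162, 91 were set apart by 1 library, such as Rlim at 96.4 CPM (here on unscaled library totals) in PDTLN1 library 1 and 394 to 412 CPM elsewhere, and Tmem127 stood at 35.7 to 37.4 CPM in control 1, control 3 and PDTLN1 3 and at 4.77 to 5.56 CPM in the others. The partition by treatment held 3 of them, no more than the highest of 8 other 3-to-3 partitions (1 to 3 each; the ninth, control 1 with PDTLN1 2 and 3, held 10), and the coding genes among the 162 had a median 3' UTR of 2420 nt against 1318 nt in sets of the same level (permutation p = 0.0001, the smallest 10000 sets can give). Of 3 overlapping pairs, 2 lay at opposite levels, Zbtb9 with Ggnbp1 and Scamp4 with Adat3. A candidate explanation for Dcbld2, Ipmk and Ppp1cb is therefore that part of a gene's reads was counted in some libraries and not in others; an induction by the peptide gives the same values and stays open.

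The split that called 831 genes set control library 1 and PDTLN1 libraries 2 and 3 against the others, which points to a structure of the samples that the labelled treatment does not follow. Removing GC content and length trends left 825 genes, and thinning to equal depth 807, which argues against either as the cause. The GC content and length correction also ended the call of Ppp1cb, whose log2 fold change went from 0.97 (SE 0.10, edgeR adjusted p 0.0459) to 0.92 (SE 0.11, 0.119, against 3.10e-13 to 0.449 over its alternatives), a slightly smaller fold with a wider error near the threshold. An exchange of the 2 libraries numbered 1 could give this split: control 1 correlated at 0.987 with PDTLN1 2 and 3 and at 0.983 with the other controls, PDTLN1 1 at 0.988 with control 2 and 3 and at 0.983 with the other PDTLN1 libraries, and the labelled split called 3 genes, no more than the highest of the 8 remaining splits. By other counts the labelled split did stand above those 8 splits. It had 4 members past their list alone, against up to 2, and 3 lists past mixed fry, against up to 1. For lists past camera it had 2, against up to 7. These small counts do not decide for or against an exchange. A difference in culture state between the libraries would look like an exchange, and the 2 cannot be told apart, because the labels give no batch and the data hold no independent marker of treatment. No biological explanation was tested.

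Id1, Id2 and Id3 separated the groups, as did 9.79% of all tested genes. Id1, Id2 and Id3 were not among the 162 genes at 2 levels, but that rule asks for a gap above 0.6 log2 units. With log2 fold changes of -0.51, -0.47 and -0.49 they could not meet it by treatment, so their absence says nothing about how they were counted. With the first principal component as a covariate, a choice made after seeing the data, Id1 had a log2 fold change of -0.52 and an edgeR adjusted p of 0.0417 over all genes, in a range of 7.73e-04 to 1.00 over its alternatives. Id2 and Id3 did not pass in that fit, with log2 fold changes of -0.38 and -0.41 and adjusted p of 0.352 and 0.202, in ranges of 0.0451 to 1.00 and 0.0211 to 1.00. No explanation was tested for these genes.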
